A study of Mus musculus with 30 samples.

How the data were processed

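Gene expression was measured in 30 single muscle fibres on 1-colour Agilent mouse microarrays, each fibre on an array of its own. Per the labels, the fibres came from the extensor digitorum longus, a fast hindlimb muscle, of adult male CD1 mice, freed with collagenase and picked by hand; fibres of injected muscles were selected for the green fluorescent marker carried by the adeno-associated virus. Per the labels, part of each fibre's RNA was first used to measure MCU by quantitative PCR, and the RNA of fibres that showed the intended change was amplified with a whole-transcriptome kit and labelled with random primers, so that the strand of a transcript was not kept. Amplification and selection limit how far signal stands for transcript number, and the change of Mcu itself is not independent of how the fibres were chosen.

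The deposited scanner files hold, per the file headers, spot intensity from Agilent Feature Extraction 10.7.3.1, in which the processed intensity of a spot had been background-subtracted and detrended within the array, with a substitute value where a spot was not above background; no scaling between arrays had been applied. Spot flags for control type, signal well above background, saturation and outlier pixels were used as the deposited files give them, per the file headers. The submitters' processed values in the deposited series matrix were intensity on a linear scale. Their distributions were nearly the same on all arrays (medians from 20.9 to 21.0), as after quantile normalization, and genes had not been centred; the labels do not state the steps. Each of the 30 columns correlated best, across probes, with its own array's scanner values (r at least 0.998, against at most 0.981 with any other array). The series matrix served as an alternative.

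Each array held 59305 spots that were not controls, for 55681 different probes. Names were updated through a table of RefSeq genes: 26425 probes were named by accession, 3988 by current symbol and 826 by synonym, and 24442 kept the name in the files, so that 3902 probes carry a name other than the deposited one. Probe positions are those of the files, on mouse build mm9. Control spots and spots with outlier flags were left out and replicate spots of a probe were averaged as log2 values. Values at or below 0 would have been set to the lowest positive signal of the array. The main value was log2 of the processed intensity minus the 75th percentile of all non-control probes on the array. Probes well above background on at least 3 arrays of at least 1 group were kept (33164 probes), and a gene was represented by its kept probe with the highest mean, which left 23342 genes.

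The 8 groups are wild type, MCU vector, transfected control and MCU-silencing vector fibres at 7 and 14 days. A linear model with 8 group means was fitted to all 30 arrays with limma 3.58.1 in R 4.3.3 (files read with the package data.table, 1.17.8), with moderated statistics (22 residual degrees of freedom), 2-sided p-values and Benjamini-Hochberg adjustment over all genes tested; a gene passed at an adjusted p below 0.05. Effects over both days are the mean of the effects at day 7 and day 14. Of the 30 gene lists fixed before the data were examined, which cover metabolism, contraction, growth and breakdown of muscle, stress, immunity and markers of other cell types, each was tested with limma's camera at a preset correlation of 0.01, with an estimated correlation and fry beside it, on 23298 genes without missing values and with adjustment over the 30 lists. Figures were drawn with matplotlib.

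Array position limits the comparisons. The 4 slides held wild type and MCU fibres of day 7, the same of day 14, transfected control and silenced fibres of day 7, and the same of day 14. Treated and control fibres of a comparison therefore shared a slide, but lay in different columns of it, while transfected control and wild type fibres never shared a slide, and for them batch and group cannot be told apart. Animals are not named, so p-values measure the spread between fibres, which may share an animal. Same-numbered fibres of a treated group and its control deviated together weakly at most (correlations from -0.175 to 0.186, above 0.1 in 4 of 14 pairs). In several pairs the same-numbered control was still the closest of its group. The numbers were not taken to pair fibres, and replicate number was a block in an alternative. The highest correlation between fibres of a group was 0.984, and none were identical.

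Genes named in the text were chosen by a rule fixed before the data were examined: Mcu; in each comparison over both days the 10 largest rises and 10 largest falls among genes that passed, leaving out names without a gene symbol; up to 4 members of each list with the largest moderated statistic; and in the other comparisons the 5 smallest p-values in each direction. Not every gene taken by this rule is named in the text. After the arrays had been seen, the largest changes were limited to genes whose probe was well above background on at least 1 array of every group compared, and up to 5 genes per direction with an undetected group were added. For these the fold is a lower bound: a group with no array well above background enters with each value raised to at least the lowest signal well above background on that array, taken at the probe that represents the gene. In a bound, dim spots of a partly detected group on the lower side are raised to this floor too. Where a difference rests on a group that only some arrays detected, the text gives the number of arrays and, where it changes, the difference with dim spots at the floor; both were chosen after seeing the data. For an array, the number of fibres and the signal over background limit the precision.

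The alternatives were other scalings (quantile, array median, percentile over probes detected everywhere), normexp background correction with an offset of 50, the series matrix, other filters on dim probes (none, or detection on at least 15 arrays), outlier spots kept, the mean over a gene's probes, a variance trend, array weights, fits of only the groups compared, the replicate number, slide row, slide or share of detected probes in the model, another control group, and each fibre left out in turn. Wild type as control for silencing, a covariate of the myosins Myh4 and Myh1, and list tests of silencing at 7 days in place of both days were added after seeing the data. In these list tests the fibres of day 14 stayed in the model. The fits were tested on simulated data with 100 genes changed per size among 23342: for overexpression over both days 75% were recovered at a log2 change of 1 and 98% at 2, with 6 false calls, and for silencing 77% and 94%, with 11 false calls.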

Results

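Transcript levels were measured in 30 single fibres of the extensor digitorum longus, a fast hindlimb muscle of the mouse, whose muscles had or had not received an adeno-associated virus (AAV) that changes MCU. MCU is the pore-forming subunit of the mitochondrial calcium uniporter, through which calcium enters the mitochondrial matrix. At 7 days there were 4 wild type fibres, 3 with the MCU vector, 4 transfected controls and 3 with a vector that silences MCU. At 14 days each of these groups had 4 fibres. The sample titles give the transfected controls a hairpin against luciferase, while other labels describe virus alone, and the sources do not settle which applies. The 75th percentile of spot signal ranged from 82.5 to 136 between arrays, and 49.3% to 59.5% of probes were well above background. The number of arrays limits the precision. All levels are log2 signal relative to the array's 75th percentile, and differences are log2 differences between group means with their standard error (SE).

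Across genes, the correlation between fibres of a group ranged from 0.951 to 0.984, and between fibres of different groups it reached 0.980. The first principal component held 17.6% of the variance and placed the 8 transfected control fibres between 35.9 and 60.6 and the 8 wild type fibres between -44.1 and -23.9. These groups were never on the same slide.

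Mcu itself answers how far each vector changed its target. The probe (named by the older symbol Ccdc109a in the files) lies on chromosome 10 from 58929203 to 58929262 in build mm9, and its 60 bases read as 20 codons without a stop. In wild type fibres Mcu stood at 2.67 ± 0.20 (SD, n = 4) at 7 days and 2.46 ± 0.27 (SD, n = 4) at 14 days. With the MCU vector it stood at 3.27 ± 0.28 (SD, n = 3) and 6.36 ± 0.35 (SD, n = 4). With the silencing vector it stood at 0.49 ± 0.97 (SD, n = 3) and -0.52 ± 1.10 (SD, n = 4), against 2.57 ± 0.34 (SD, n = 4) and 2.55 ± 0.22 (SD, n = 4) in transfected controls. All 7 fibres with the MCU vector lay above, and all 7 silenced fibres below, every control fibre of their day.

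Over both days the MCU vector raised Mcu by 2.25 (SE 0.28, adjusted p = 7.9e-06). The difference was 3.90 (SE 0.38, adjusted p = 4.0e-06) at 14 days and 0.60 (SE 0.41, adjusted p = 0.999) at 7 days, where it did not pass. The change between days, 3.30, passed (SE 0.56, adjusted p = 0.0034). Silencing lowered Mcu on both days, by a mean log2 difference of -2.58 (SE 0.28, adjusted p = 2.7e-06), with -2.08 at 7 days (adjusted p = 0.0016) and -3.07 at 14 days (adjusted p = 1.7e-05). Transfected controls and wild type fibres differed by -0.00 (SE 0.27, adjusted p = 0.994). Because fibres were selected by their MCU transcript before hybridisation, these differences are not independent of the selection. The sequence of the insert is not given, so vector and native transcript were not separated.

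**Figure D1:**
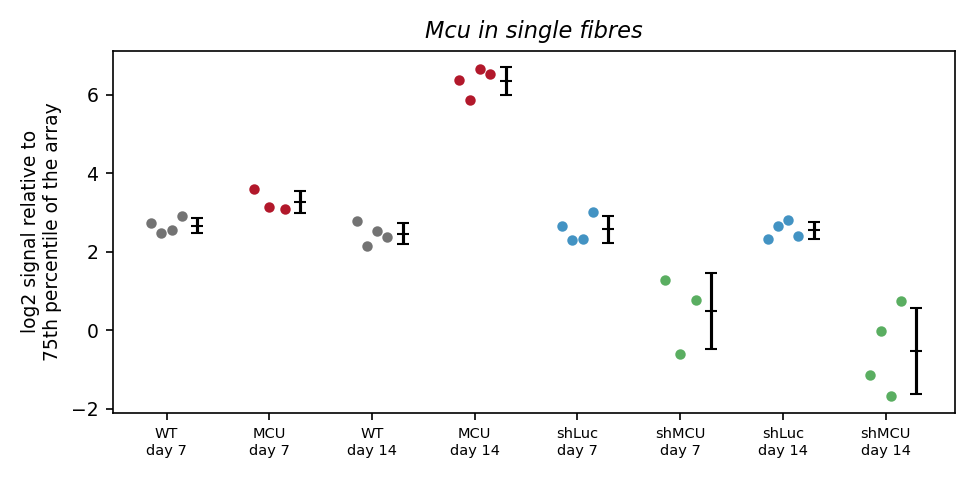
Level of Mcu in every fibre, as log2 signal relative to the 75th percentile of the array (y axis), by group and day (x axis); points are fibres and bars are group means ± SD. Fibres with the MCU vector stand between 5.87 and 6.66 at 14 days, and silenced fibres stand between -1.69 and 1.28 over both days.

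The comparison of MCU-vector with wild type fibres asks which transcripts change with the vector that raises MCU. Wild type fibres carried no vector, so the difference holds the virus and its marker as well as MCU. Over both days the largest rises were immune genes. Igtp, an interferon-inducible GTPase, rose 26.9-fold (log2 4.75, SE 0.35, adjusted p = 2.2e-09). Its relative Irgm2 rose 16.0-fold (log2 4.00, adjusted p = 3.5e-08), and the guanylate-binding proteins Gbp11 and Gbp7 rose by 3.63 (SE 0.88, adjusted p = 0.038) and 3.02 (adjusted p = 1.3e-06). Genes that present antigens rose with them: Cd74, the invariant chain of class II, by 3.39 (SE 0.30), the class I heavy chains H2-K2 by 3.17 and H2-Q2 8.56-fold, their light chain B2m by 2.89 (SE 0.25, adjusted p = 1.6e-08), and the immunoproteasome subunit Psmb8 by 3.17. Ifit3, an antiviral interferon target, rose by 3.16 (SE 0.25). Gbp11 and Psmb8 were well above background on 10 of 15 arrays and Ifit3 on 12, with 1 of 4 in a wild type group of each, and with the dim spots at their array's lowest detected signal, the floor, the differences were 3.02, 3.02 and 2.98. Genes whose wild type probes were not well above background on any array of a day can only be bounded: Parp14 was at least 9.7-fold higher, Irf7 at least 4.2-fold, Serpinb1c at least 4.2-fold, H2-DMb1 at least 3.8-fold and H2-Aa at least 3.7-fold. H2-Aa and H2-DMb1 were well above background on 4 of 15 arrays, 3 of them at 7 days. At 7 days they were at least 21.7-fold and 17.8-fold higher, and at 14 days their effects were lower by at least 3.4-fold and 4.5-fold. Their bounds over both days therefore rest on 7 days. For Parp14 the bounds were 54.8-fold at 7 days and 1.7-fold at 14 days, and for Serpinb1c 2.7-fold and 6.6-fold. Irf7 was at least 9.7-fold higher at 7 days, with a log2 difference of 0.92 at 14 days that did not pass. H2 genes share much sequence, so a probe can read a relative of the gene named.

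The falls in MCU-vector fibres were smaller and fewer. The heat shock genes Hspa1a and Dnajb1 fell by 2.26 (SE 0.56, adjusted p = 0.044) and 2.01 (SE 0.40, adjusted p = 0.0064). Nmrk2, a muscle kinase of NAD synthesis, fell by 1.40 (adjusted p = 0.014). Unc45bos fell by 2.04, Lmo2 fell by 1.11, Tmem37 fell by 1.06, the collagen chaperone Serpinh1 fell by 0.85 and Olfr1115 fell by 0.73. Unc45bos and Olfr1115 were well above background on 11 and 12 of 15 arrays, and with dim spots at the floor fell by 1.68 and 0.64. Bounded falls were at least 2.99-fold for Slc15a5, 1.6-fold for Fzd6, 1.4-fold for Itgb4, 1.2-fold for Scml4 and 1.2-fold for Rap1gap.

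In all, 195 genes were higher and 68 lower with the MCU vector (263 of 23342, limma), 89 of them at least 2-fold among genes measured in every group. Of the called genes 74.1% were higher, against 87.2% when arrays were scaled by their median, 63.7% over probes detected on all arrays and 60.4% with normexp background correction (492 genes). The count was 1298 with array weights, 533 with the Myh4 and Myh1 covariate, 172 without MCU day 7 replicate 1 and 171 without replicate 2. It was 6057 against the transfected control, which was on other slides, so that slide and group cannot be told apart.

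Of the gene lists, antigen presentation moved furthest with the MCU vector. Of its 15 measured members 12 rose and none fell, or 13 adjusted over the list alone, with a median of 2.16, or 1.89 with undetected groups at their bound (camera adjusted p = 2.2e-41, and 2.4e-06 with an estimated correlation). Of 18 interferon and antiviral genes 9 rose, or 13 adjusted over the list alone, with a median of 0.94, or 1.01 at the bound (adjusted p = 2.3e-22, and 5.2e-08 with an estimated correlation). H2-K1 (2.79), H2-T23 (2.16), Xaf1 and Ifit3 were among the members that rose. Both medians were positive under every scaling, from 1.52 to 2.20 and from 0.46 to 1.02. Apart from satellite cell markers, lists of other cell types did not pass: macrophage and myeloid markers (adjusted p = 0.867), lymphocytes (0.541), fibroblasts (0.175), endothelium (0.350), mural cells (0.948), Schwann cells (0.567), adipocytes (0.619) and erythroid cells (0.370).

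Muscle lists moved less in MCU-vector fibres, and none of the following calls held with an estimated correlation. Excitation-contraction coupling genes were higher as a list (adjusted p = 2.5e-07, 0.508 with an estimated correlation), with a median of 0.22. Of its 33 members 3 rose, or 6 adjusted over the list alone: Srl, a calcium-binding protein of the sarcoplasmic reticulum, by 0.54 (adjusted p = 0.0015), the calcium channel subunit Cacna2d1 by 0.58 and the kinase Camk2d by 0.74. No member of OXPHOS complex I, whose subunits feed electrons into respiration, passed in limma, and 8 of 36 were lower at an unadjusted p under 0.05. The list was lower with a median of -0.19 (adjusted p = 2.5e-07, 0.590 with an estimated correlation). Complexes II to V had a median of -0.20, with 0 of 41 members past the threshold and 8 lower before adjustment (adjusted p = 2.3e-08, 0.590 with an estimated correlation). The TCA cycle had a median of -0.17 (adjusted p = 0.0016, 0.636 with an estimated correlation), with 0 of 26 called, 6 lower and 1 higher before adjustment, and 3 lower adjusted over the list alone. Fatty acid oxidation had a median of -0.29 (adjusted p = 0.00062, 0.640 with an estimated correlation), with 0 of 27 called and 1 lower before adjustment.

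The remaining lists called in MCU-vector fibres had 2 or fewer members past the threshold. Fast sarcomere genes had a median of 0.17 (adjusted p = 0.0099, 0.590 with an estimated correlation), atrophy genes 0.18 (0.014, 0.590 with an estimated correlation), proteasome subunits 0.13 (0.00017, 0.636 with an estimated correlation) and IGF1 growth signalling 0.09 (0.0465, 0.493 with an estimated correlation). In these 4 lists no member passed in limma, while before adjustment 2, 7, 5 and 6 members were higher and 1 atrophy and 2 growth genes lower, and 2 atrophy genes rose adjusted over the list alone. Immediate-early genes had a median of -0.30 (0.0198, 0.673 with an estimated correlation), and only Hspa1a and Dnajb1 fell. MCU-vector day 7 replicate 1 stood apart from replicates 2 and 3, with Rrad at 3.68 against -0.36 and -0.48, Myc at 1.62 against -1.45 and -1.81, Ankrd1 at 4.12 against 0.81 and -1.61, and the first principal component at 0.96 against -33.0 and -42.9. Among satellite cell markers, with a median of 0.23 (0.0365, 0.508 with an estimated correlation), 1 of 5 rose: Des, the desmin of muscle intermediate filaments, by 0.60 (adjusted p = 9.7e-05). Lists without a call were the MCU complex (adjusted p = 0.434; only Mcu rose), glycolysis (0.237), slow sarcomere (0.201), autophagy (0.434), mitochondrial biogenesis (0.350), ribosomal proteins (0.948), ER stress (0.0791), antioxidant defence (0.434) and denervation (0.0692).

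Day by day, immune genes were higher at 7 than at 14 days of the MCU vector. Mcu itself was higher by 0.60 at 7 days, which did not pass, and by 3.90 at 14 days. At 7 days 9 interferon genes rose (median 1.88, adjusted p = 2.1e-10 with an estimated correlation) and 12 antigen presentation genes (median 3.17, 1.1e-08 with an estimated correlation). At 14 days 1 interferon gene rose (median 0.25, adjusted p = 0.0283 with an estimated correlation) and 5 antigen presentation genes (median 0.53, 0.0903 with an estimated correlation). The difference between days was tested itself: 4 interferon and 7 antigen presentation genes fell, with medians of -1.56 (adjusted p = 3.1e-08 with an estimated correlation) and -1.41 (1.1e-06 with an estimated correlation). Igtp was higher by 6.76 at 7 days and by 2.74 at 14 days, a difference of -4.03 (adjusted p = 0.0041). For H2-K1 (3.49 and 2.08) and B2m (3.57 and 2.21) the difference between days did not pass (adjusted p = 0.50 and 0.97). Transfected controls, on other slides, were also higher than wild type at 7 and 14 days. There Igtp was higher by 0.99 and 2.66, B2m by 1.37 and 1.30 and H2-K1 by 0.51 and 0.77.

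**Figure D2:**
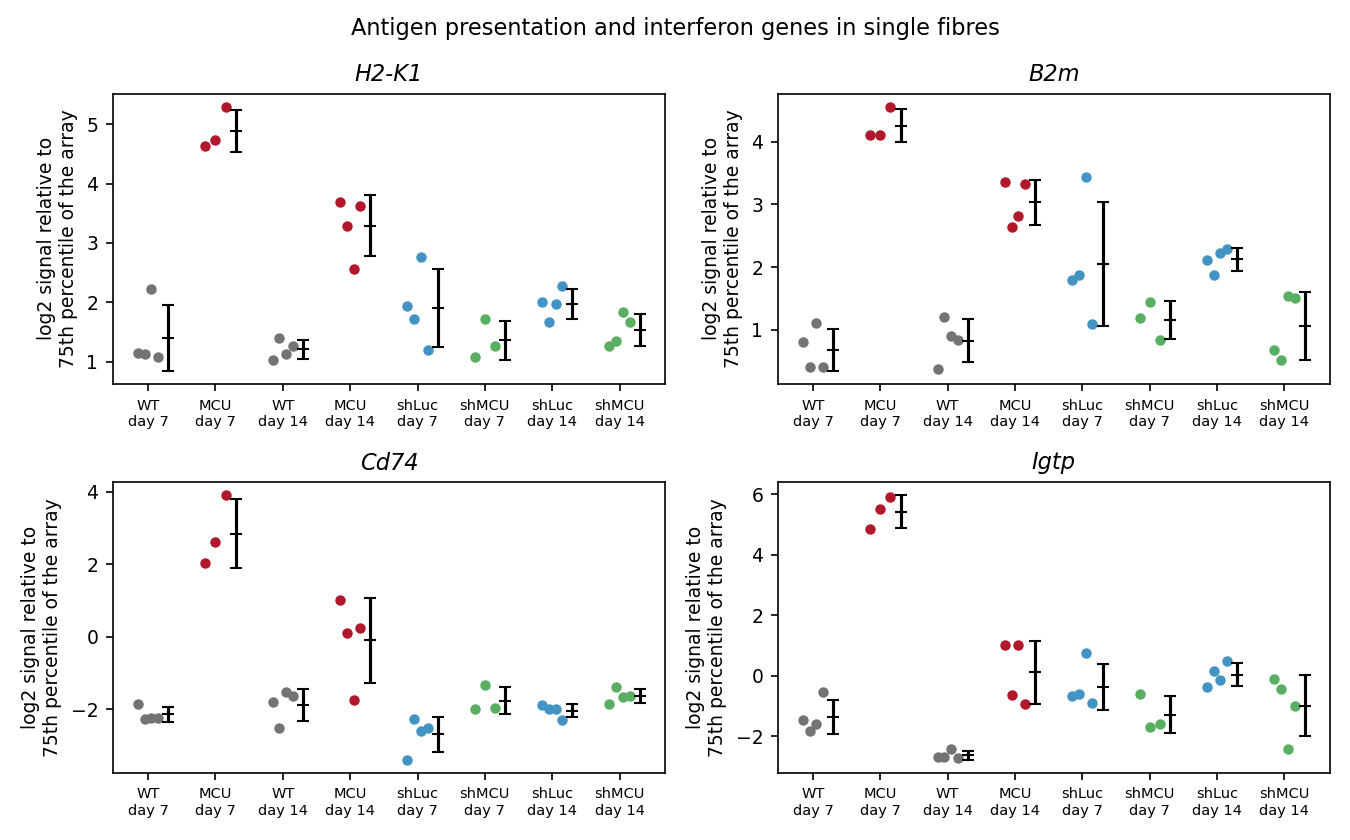
Levels of H2-K1, B2m, Cd74 and Igtp in every fibre, as log2 signal relative to the 75th percentile of the array (y axis), by group and day (x axis); points are fibres and bars are group means ± SD. H2-K1 stands between 4.64 and 5.29 in MCU-vector fibres at 7 days and between 1.08 and 2.23 in wild type fibres of that day; Cd74 overlaps between groups at 14 days, from -1.75 to 1.02 against -2.51 to -1.53.

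At 7 days 126 genes were higher and 8 lower with the MCU vector. Those with the smallest p were Iigp1b (at least 31-fold), Xaf1 (at least 8.5-fold), Cd274, the immune checkpoint ligand PD-L1 (at least 7.9-fold), Iigp1 (2.84) and Cep162 (2.03, with another probe of the opposite sign). Clec14a (-1.03, adjusted p = 0.011) and Thnsl1 (-0.50, adjusted p = 0.038, with another probe of the opposite sign over both days) fell. The other 6 lower genes that passed carry no gene symbol, and Itgb4 and H2ax did not pass. At 14 days 77 genes were higher and 23 lower (77.0% higher, 88.5% with median scaling). Beside Mcu, Rftn1 (1.84), H2-D1 (2.41), H2-K1 (2.08) and Nup133 (1.47) rose, each with an adjusted p of 0.00053. Slc15a5 was at least 6.2-fold lower (adjusted p = 0.0068), and Dnajb1 (-2.86, adjusted p = 0.010), Fkbp7 (-1.31), Slco1a4 (-1.14, or -0.87 with dim spots at the floor, 5 of 8 arrays detected) and Tmem37 (-1.55) fell. Of the genes higher on a day, 32 were higher on both, against 0.416 expected if the sets were independent. The effect differed between days for 47 genes, 4 higher and 43 lower at 14 days, and Wdr1 and Myl9 did not pass.

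Across genes, the effects of the MCU vector at 7 and 14 days correlated with r = 0.365; 1 of 100 relabellings of fibres within slides, the real one included, gave an r as large, and the others ranged from -0.317 to 0.323. Genes are not independent replicates. The 14-day count fell from 100 to 60 with only the groups compared, 39 with the share of detected probes as covariate, 45 without wild type replicate 3 and 61, 58 or 48 without MCU-vector replicate 2, 3 or 4; it was 392 with array weights and 568 with the myosin covariate. The 7-day count was 343 with array weights, and the count of day differences ranged from 28 to 96, with 30 without MCU-vector day 7 replicate 3.

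The comparison of silenced fibres with transfected controls asks which transcripts change when MCU is lowered. The largest falls were of Rrad, a GTPase that inhibits calcium channels, by 4.25 (SE 0.53, adjusted p = 2.3e-05), Vasn (-3.79), Cgref1 (-3.68), the sphingosine kinase Sphk1 (-3.56, adjusted p = 6.6e-06) and the phosphatase inhibitor Ppp1r1c (-3.32, SE 0.19, adjusted p = 3.2e-11). Ankrd1, a titin-associated protein induced by muscle stress, fell by 3.29 (adjusted p = 0.00053), and the growth regulator Myc fell by 3.05 (adjusted p = 0.00066). Thbd (-3.24) and Gem (-3.20) fell as well. However, another probe gave 0.02 for Gem and -0.81 for Vasn. Vasn and Cgref1 were well above background on 11 of 15 arrays, Gem on 12 and Ppp1r1c on 13, and with dim spots at the floor fell by 3.58, 3.14, 2.84 and 3.14. Bounded falls were at least 8.1-fold for Fosl1, 6.1-fold for Plk2, 5.9-fold for Sh3bp2, 5.1-fold for Sgms2 and 3.5-fold for Timp1.

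Among genes that rose in silenced fibres, the chemokine receptor Cxcr6 rose by 2.86 (SE 0.42, adjusted p = 0.00011), the glutathione transferase Mgst1 by 2.12, Sowaha by 1.98, Lmcd1 by 1.98, Tmem14c by 1.66 (SE 0.14, adjusted p = 6.8e-08), the aldehyde dehydrogenase Aldh9a1 by 1.62, the carboxylesterase Ces1d by 1.55 and Batf2 by 1.51. The effect on Tmem14c changed by -3.00 from 7 to 14 days, and its level also differed between wild type fibres of 7 and 14 days. Ighv14-2 (2.07) and Igh-VJ558 (1.72) also rose, with other probes of the opposite sign. With dim spots at the floor the rises were 2.36 for Cxcr6 (detected on 11 of 15 arrays), 1.81 for Mgst1 (13), 1.24 for Ces1d (12), 1.60 for Aldh9a1 (14) and 1.95 for Ighv14-2 (14). Ifit3 was at least 6.2-fold higher, Ifit3b at least 2.7-fold, Rnf26 and Zfp52 at least 2.5-fold and Cep250 at least 1.4-fold.

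For Rrad, Ankrd1 and Myc the means of silenced fibres lay above those of wild type fibres on both days. Rrad stood at 0.52 and 0.31 in silenced fibres of 7 and 14 days, at 4.49 and 4.84 in transfected controls and at -0.39 and -0.35 in wild type fibres. Ankrd1 stood at 0.76 and 2.03, against 4.56 and 4.80 in transfected controls and -0.09 and 0.66 in wild type. Myc stood at -1.40 and -1.02, against 2.14 and 1.54 in transfected controls and -1.44 and -2.26 in wild type.

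**Figure D3:**
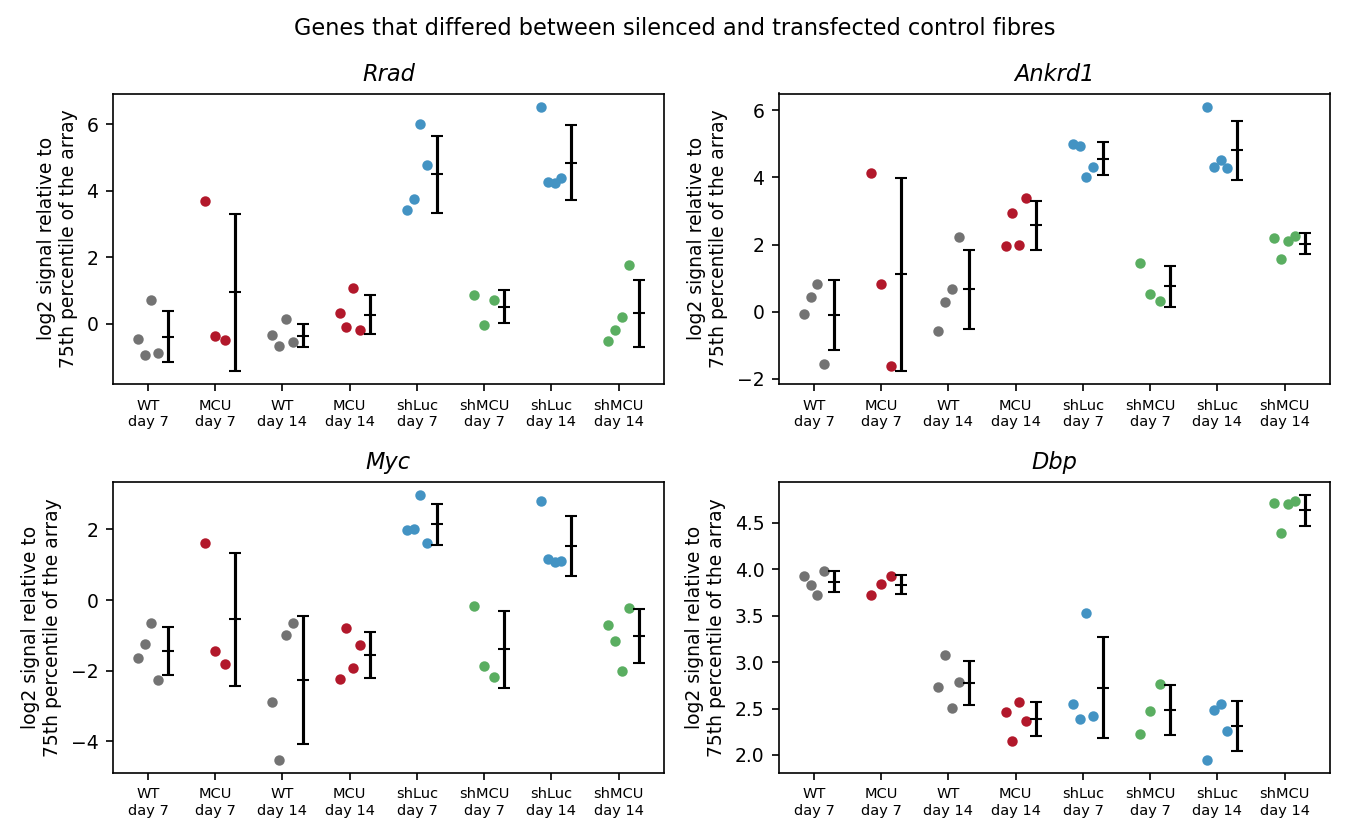
Levels of Rrad, Ankrd1, Myc and Dbp in every fibre, as log2 signal relative to the 75th percentile of the array (y axis), by group and day (x axis); points are fibres and bars are group means ± SD. Transfected controls stand highest for Rrad, Ankrd1 and Myc, with Rrad means of 4.49 and 4.84, and silenced fibres of 14 days stand highest for Dbp, from 4.39 to 4.73.

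In all, 1867 genes were higher and 1425 lower in silenced fibres (3292), 438 of them at least 2-fold among genes measured in every group. The share of higher genes depended on scaling: it was 56.7%, 25.1% with scaling by the median and 74.5% over probes detected on all arrays, where the median over all genes was 0.11. With only the groups compared, the count was 1612, 799 higher and 813 lower. Against wild type fibres, which were on other slides, 1163 were higher and 1877 lower.

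Of the lists called in silenced fibres, IGF1 growth signalling, immediate-early, atrophy, excitation-contraction coupling, denervation and autophagy genes were lower, and complex I, complexes II to V and fatty acid oxidation higher. IGF1 growth signalling was lower with a median of -0.20 (adjusted p = 0.0003), the only list whose call held with an estimated correlation (0.0481). In transfected controls the same list was higher than in wild type, with a median of 0.33 (adjusted p = 0.002, 0.144 with an estimated correlation), as were the other 5 lists that were lower here. Of its 35 members 8 fell and 1 rose, or 9 and 1 adjusted over the list alone. Those that fell include Myc, the insulin receptor substrate Irs2 (2.01-fold lower), the translation factor Eif4g1 (-0.47) and the kinase Akt2 (-0.40). The 3 Akt2 probes ranged from -0.40 to -0.01. Immediate-early genes had a median of -0.65 (adjusted p = 4.9e-05, 0.634 with an estimated correlation), and 7 of 25 fell, or 9 adjusted over the list alone, among them Klf6 (-1.94) and Nr4a1 (-0.84). Of 25 atrophy genes 7 fell and 1 rose, or 9 and 1 adjusted over the list alone (median -0.24, adjusted p = 0.00057, 0.493 with an estimated correlation). They include the ubiquitin ligase Trim63 (-1.43, adjusted p = 0.00016), the transcription factor Foxo1 (-0.60), and the metallothioneins Mt2 (-1.79) and Mt1 (-1.51, with probes of both signs).

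Of 33 excitation-contraction coupling genes 7 fell, or 8 adjusted over the list alone (median -0.32, adjusted p = 4.3e-06, 0.555 with an estimated correlation), among them Srl (-0.41) and the calcium sensor Stim2 (-1.07). Of 19 denervation and junction genes 6 fell, or 7 adjusted over the list alone (median -0.32, adjusted p = 0.0005, 0.335 with an estimated correlation): the myogenic factor Myod1 fell by 0.89, Runx1 fell by 1.81 (1.33 with dim spots at the floor, detected on 9 of 15 arrays) and the acetylcholine receptor subunit Chrnb1 fell by 0.56. Autophagy had 3 falls, including Gabarapl1 (-0.88), and 1 rise (median -0.15, adjusted p = 0.0075, 0.555 with an estimated correlation).

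Complex I rose in 10 of 36 members, or 15 adjusted over the list alone, with a median of 0.27 (adjusted p = 7.2e-07, 0.755 with an estimated correlation), for example Ndufa7 (0.36) and Ndufs8 (0.63). Complexes II to V rose in 11 of 41, or 22 adjusted over the list alone, with a median of 0.25 (adjusted p = 7.2e-07, 0.755 with an estimated correlation), for example Cox7b (0.38) and Atp5o (0.39). Fatty acid oxidation rose in 5 of 27, or 9 adjusted over the list alone, with a median of 0.47 (adjusted p = 0.00011, 0.755 with an estimated correlation), for example Etfb (0.62) and Acadm (0.65). The medians of the called lists kept their sign under every scaling.

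Lists without a call still held genes that changed. Of 26 glycolysis genes (adjusted p = 0.293) the glucose transporter Slc2a1 (-2.54), hexokinase Hk2 (-1.06) and Pfkfb3 (-1.03) fell and the muscle glucose transporter Slc2a4 rose by 0.32. Of 23 antioxidant genes (0.293) Hmox1 (-2.27), Txnrd1 (-0.88), Nfe2l2 (-0.92) and Srxn1 (-2.21) fell. B2m (-0.98) and H2-D1 (-0.84) fell among antigen presentation genes (0.313), whose median was 0.05 and mean -0.08. Interferon genes had 4 falls and 1 rise (0.702). Myl2 (-0.99, or -0.91 with dim spots at the floor, detected on 14 of 15 arrays) fell among slow sarcomere genes (0.702). Of mitochondrial biogenesis genes (0.176) Tfb1m (detected on 13 of 15 arrays) rose by 1.01 and 1 gene fell. Of the MCU complex (0.501) 2 fell, including Mcu, and 1 rose.

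In the TCA cycle list 1 gene rose (adjusted p = 0.293), in the ribosomal list 2 rose and 1 fell (0.693) and in the ER stress list 1 rose and 1 fell (0.943). No fast sarcomere gene (0.870) or proteasome subunit (0.293) passed in limma; before adjustment 2 fast sarcomere genes were higher and 2 lower, and 1 proteasome gene was lower. Markers of other cells did not pass as lists: macrophages (0.702; Cd68 fell by 2.11 and C1qb fell by 0.53), lymphocytes (0.531; 2 rose), satellite cells (0.0668; 1 fell), mural cells (0.313; Cspg4 rose by 0.93), Schwann cells (0.702; 1 rose), adipocytes (0.501; 1 rose), fibroblasts (0.773), endothelium (0.693) and erythroid cells (0.844).

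Silencing called more genes at 7 days, 1932 higher and 1207 lower, than at 14 days, 360 higher and 447 lower. At 7 days Ifit3 was at least 12.3-fold and Ifit3b at least 6.4-fold higher, Tmem14c rose by 3.16, Glud-ps by 2.47 and Cspg4 by 2.19. Ppp1r1c (-4.12, or -3.74 with dim spots at the floor, detected on 5 of 7 arrays), the potassium channel partner Abcc9 (-2.39), Zg16 (-2.87) and the transcription factor Stat3 (-1.93) fell, and Zfp33b was at least 3.5-fold lower. At 14 days Abcc9 (2.58), the clock output gene Dbp (2.32), Usp2 (1.20), the mitochondrial import factor Chchd4 (1.77) and Cep85l (1.87) rose. Ppp1r1c (-2.53), Myod1 (-1.20) and Zfp931 (-1.05) fell, Gdpd3 was at least 9.9-fold lower, and Espn at least 5.0-fold lower by a probe whose sign another probe did not share.

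Of respiratory genes, 13 of complex I and 18 of complexes II to V rose at 7 days (adjusted p = 0.517 for both lists with an estimated correlation). At 14 days no member of either list passed in limma, with 1 complex I gene higher and 1 lower and no gene of complexes II to V before adjustment. The difference between days passed for 4 and 2 members, all lower at 14 days (adjusted p = 0.918 for both lists with an estimated correlation). Of the silenced fibres at 14 days, replicate 3 had Myh4, the main fast myosin, at 0.37 and replicate 1 at 5.92, while every other fibre of the series stood between 7.19 and 7.97. Myh1, another fast myosin, was higher by 4.03 at 14 days (adjusted p = 0.0703), 0.96 at 7 days (0.676) and 2.50 over both (0.0677), none of which passed.

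Between days 81 genes were higher at both, against 29.8 expected, and 127 were lower at both, against 23.1 expected if the sets were independent. The effect differed between days for 963 genes, 322 higher and 641 lower at 14 days. Across genes the effects of silencing at 7 and 14 days correlated with r = 0.260, which 4 of 100 relabellings, the real one included, reached in size (others from -0.346 to 0.257). The share of higher genes at 7 days was 61.5%, 37.9% with median scaling and 72.6% over probes detected on all arrays (median over all genes 0.14); at 14 days it was 44.6%, 22.4% (median over all genes -0.13) and 64.4%. The 7-day count fell from 3139 to 1818 with array weights, 851 with only the groups compared and 1900 without silenced replicate 3. The 14-day count fell from 807 to 130 with only the groups compared, 424 with the myosin covariate, 528 without control replicate 4 and 476 without silenced replicate 3. It was 2353 against wild type, which was on other slides.

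Transfected controls were compared with wild type fibres to show what the control itself carries. In the controls 18 of 25 immediate-early genes rose and 2 fell (median 1.43, adjusted p = 4.2e-09, 0.221 with an estimated correlation). Rrad was higher by 5.04, Ankrd1 by 4.40, Myc by 3.69 (3.47 with dim spots at the floor, detected on 15 of 16 arrays), the haem oxygenase Hmox1 by 3.02, Mt2 by 5.15 and Trim63 by 1.66. The smallest p belonged to Gstt3 (at least 7.2-fold higher), Stat3 (1.86, SE 0.13, adjusted p = 2.9e-09), Ppp1r1c (2.49, or 2.40 with dim spots at the floor, detected on 14 of 16 arrays), Usp28 (2.02) and Sphk1 (4.78), and among lower genes to genes that include Flvcr2 (-0.99), Cnnm2 (-0.98), Lypd6b (-1.19, detected on 15 of 16 arrays) and Traip (-0.92).

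Other lists called in transfected controls also lost the call with an estimated correlation. Of 25 atrophy genes 9 rose and 3 fell (adjusted p = 9.6e-05, 0.160 with an estimated correlation), of 28 autophagy genes 11 rose and 2 fell (0.0004, 0.160 with an estimated correlation), and of 35 IGF1 growth genes 12 rose and 3 fell (0.002, 0.144 with an estimated correlation). Of denervation genes 8 rose and 1 fell (0.002, 0.205 with an estimated correlation), of antioxidant genes 6 rose (0.0037, 0.160 with an estimated correlation) and of excitation-contraction coupling genes 5 rose (0.002, 0.582 with an estimated correlation). Of ribosomal genes 7 rose and 1 fell (0.00062, 0.732 with an estimated correlation), of proteasome subunits 4 rose (0.0037, 0.732 with an estimated correlation), and of fibroblast markers 3 fell (0.0184, 0.582 with an estimated correlation).

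In all, 2396 genes were higher and 4094 lower in transfected controls, and 843 of these 6490 differed at least 2-fold among genes measured in every group. Slide and group cannot be told apart here: the count was 2931 with slide as a random block and 3569 with the share of detected probes as covariate. The share of higher genes was 36.9%, 66.9% with median scaling, where the median over all genes was 0.12, and 23.9% over probes detected on all arrays, where it was -0.12. Of the genes higher in silenced fibres 1160 were lower in transfected controls than in wild type, against 327 expected, and of those lower in silenced fibres 783 were higher in transfected controls, against 146 expected. The same control fibres enter both differences, so part of this overlap arises without any effect of silencing.

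The effects of the MCU vector and of silencing were set against each other. The difference between them passed for 1247 higher and 1367 lower genes. Mcu differed by 4.83 (adjusted p = 2.7e-08), Irgm2 by 5.98 and Stat3 by 2.47, and Iigp1b and Ppp1r1c were among the smallest p without a measurable fold. Tmem14c (-1.68), Olfr128 (-1.27), Zfp110 (-1.33), Krt77 (-1.57) and Cnnm2 (-0.86) had the smallest p among lower genes. Of complex I 13 members and of complexes II to V 12 were lower in this difference (adjusted p = 0.406 and 0.437 with an estimated correlation). Higher were 9 excitation-contraction coupling genes (0.182 with an estimated correlation), 8 atrophy genes, with 1 lower (0.166 with an estimated correlation), and 7 IGF1 growth genes, with 1 lower (adjusted p = 0.0102 with an estimated correlation). Higher were also 7 interferon and 13 antigen presentation genes (adjusted p = 0.000147 and 0.000821 with an estimated correlation).

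Genes higher with the MCU vector and lower with silencing numbered 52, against 11.9 expected if the sets were independent, and genes lower with the MCU vector and higher with silencing numbered 2, against 5.44 expected. Of the 52 genes 44 were also higher in transfected controls than in wild type. Of all genes higher with the MCU vector 86 were higher there, against 20 expected, and of those lower 31 were lower there, against 11.9 expected. Wild type fibres enter both of these differences and control fibres enter silencing, so the counts are not independent. Across genes the effects of the MCU vector and of silencing correlated with r = -0.269, and 7 of 100 relabellings, the real one included, gave an r as large in size, so the correlation did not stand out. The share of higher genes in the difference was 47.7%, 78.7% with median scaling and 27.2% over probes detected on all arrays, where the median over all genes was -0.18. Without MCU-vector day 7 replicate 1 the count fell from 2614 to 1704.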

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

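Tests of slide batch, animals, leukocyte RNA, the vector in general, array position, loss of MCU, fibre subtype and time of day were chosen only after the result was seen; those of regrouped samples and shared control fibres were chosen before.

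In transfected controls many genes differed from wild type, and silencing ran the opposite way across genes (r = -0.677, against -0.480 in simulations with unchanged groups that share controls). Shared control fibres do not account for this alone: with different control fibres in each difference the covariance stayed below 0 in all 36 ways of dividing them, with -0.126 as its highest value. A slide or scan batch as the whole cause would move silenced fibres like the controls on their slides, but the slope between the differences from wild type was 0.455 (0.438 to 0.479 over these divisions), where at least 0.8 was predicted, so a partial slide effect remains open. The explanation that groups came from different animals predicted that genes with 2 separate levels part silenced fibres from controls at least 5 times as often as MCU-vector from wild type fibres, and the ratio came out the opposite way, at 0.372 (10 against 42 genes at 7 days, 6 against 1 at 14 days). It is not read as excluding animals, for a reason found only after the ratio was seen: 42 of the 43 genes in its denominator are high in MCU-vector fibres of 7 days alone, and as animals are not named, animals and groups cannot be told apart.

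In MCU-vector fibres of 7 days, 33 interferon and antigen presentation genes had a median difference of 2.60 from wild type. RNA from leukocytes would bring their other transcripts, but 19 lymphocyte and myeloid markers had a median of -0.0149. Ptprc stood at -0.87 against -0.63 and Lyz2 (on 6 of 7 arrays) at -2.07 against -1.29. Csf1r stood at 4.61 against 4.63, far above both in wild type fibres too, so its level says little of leukocyte RNA. However, Cd68 was higher by 1.18 and C1qa by 1.15, neither passing. C1qa was well above background on 4 of 7 arrays, and with dim spots at the floor was higher by 0.54. A response to any viral vector as the whole cause would raise the interferon and antigen presentation genes in transfected controls too. There, at 7 days and across slides, their median difference from wild type was 0.0371. Of the 30 genes higher with the MCU vector, 2 reached 0.5 of their rise. An effect of array position would recur in silenced fibres, which lay in the same columns, where the median difference from their controls was -0.116 and 2 of the 30 genes reached 0.5 of their rise. A part played by any vector stays open, as B2m and Igtp were higher in controls than in wild type by 1.37 and 0.99 at 7 days and by 1.30 and 2.66 at 14 days, when the medians were 0.32 in controls and 0.41 with the MCU vector, and a response to MCU, to this vector preparation or to the animals injected was not tested.

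In silenced fibres of 14 days, 7 of 12 genes in a list of clock output rose and 1 fell (median 0.69). Those that rose include Dbp (2.32), Usp2 (1.20) and 2 genes of the clock's negative limb, Per3 (2.37) and Cry2 (1.04). Per3 stood from 0.08 to 0.61 in these fibres, and in wild type from 0.01 to 0.32 at 7 days and -1.49 to -0.75 at 14 days. Usp2 stood from 3.92 to 4.08, against 3.43 to 3.84 in wild type and 2.66 to 2.98 in transfected controls of 14 days. Dbp, from 4.39 to 4.73, stood above wild type fibres of 7 days (3.73 to 3.98) and 14 days (2.50 to 3.08). The list was made after Dbp had been seen. Loss of MCU as the whole cause was predicted to move the list the same way at 7 days, where Mcu was also low. There the list's median was -0.327, and 7 members differed between days. This argues only against an effect already present at 7 days. An effect that needs more time, or a deeper loss of Mcu (-2.08 at 7 days, -3.07 at 14 days), is not excluded. Fibre subtype is argued against, since the median with the Myh4 and Myh1 covariate was 0.622. The positive limb of the clock had a median of -0.498, opposite to the output list, with Arntl at least 3.0-fold lower. With undetected groups at their bound that median was -0.10, over 5 genes. Sampling at another time of day, or another animal, may be the source. Any other shift of the clock would also move the lists apart, so their signs do not decide between these causes. Times of sampling are not given.

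Each of a set of chosen genes was tested in each group of 4 fibres for a fibre apart from the other 3. This held in 15 of 132 such tests, where chance gives about 1 in 20. The criterion is the gap relative to the range of the group, so some gaps are small. Several of the 15 fall on the same fibre, so the tests are not independent. In transfected controls these were Pvalb in day 14 replicate 2 (10.37, others 10.19 to 10.21), Dbp in day 7 replicate 3 (3.53, others 2.39 to 2.55), Usp2 in day 7 replicate 3 (3.02, others 3.16 to 3.19), Per3 in day 7 replicate 2 (-2.74, others -1.39 to -1.14), and in day 14 replicate 1 Ankrd1 (6.10, others 4.29 to 4.51), Myc (2.80, others 1.07 to 1.16) and Rrad (6.53, others 4.22 to 4.37). In silenced fibres it was Dbp in day 14 replicate 2 (4.39, others 4.70 to 4.73). In wild type fibres these were, in day 7 replicate 3, H2-K1 (2.23, others 1.08 to 1.15), Trim63 (0.87, others 1.59 to 1.65) and the haemoglobin gene Hba-a1 (3.95, others -1.29 to -0.80), with Cd74 in day 7 replicate 1 (-1.85, others -2.26 to -2.23), Igtp in day 14 replicate 3 (-2.41, others -2.72 to -2.66) and Hba-a1 in day 14 replicate 1 (4.02, others -0.62 to -0.14). Hba-a1 was also high in MCU-vector day 14 replicate 4 (4.21, others -1.02 to -0.31). In groups whose gaps did not meet the criterion, Hba-a1 stood at 6.57 and 4.35 in silenced day 14 replicates 3 and 2 and at 2.45 in transfected control day 7 replicate 4, and Pvalb stood at 6.36 in silenced day 14 replicate 3. Groups of 3 fibres were not tested.

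The effect of a vector differed between days in limma for the following named genes. For the MCU vector the change from 7 to 14 days was 3.30 for Mcu, 1.48 for Nup133, 1.79 for Rftn1, -3.06 for Iigp1 and -1.84 for Cep162, whose probes disagree in sign. Fitted changes of -6.76 for Iigp1b, -4.84 for Xaf1 and -4.94 for Cd274 involve groups without a measured level and are not folds. For silencing it was 4.97 for Abcc9, 1.45 for Usp2, 2.56 for Dbp, 2.18 for Abhd16b, 1.79 for Slc39a5, -2.98 for Glud-ps, -3.00 for Tmem14c and -1.47 for Rnase10. For Gdpd3 (-5.72, at least 13.4-fold) and Ifit3 (-4.29, at least 3.99-fold) a group was undetected.

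Other groupings of the same fibres were compared with the real one by the number of genes called. Over both days 1 of 100 splits, the real one, reached the 263 genes of the MCU vector (highest other 56), the 3292 of silencing (highest other 910), the 2614 of their difference (highest other 95) and the 6490 of transfected control against wild type (highest other 3769). At single days 1 of 35 splits, the real one, reached the 134 genes (highest other 59) and 100 genes (highest other 1) of the MCU vector at 7 and 14 days, and the 3139 (highest other 1035) and 807 (highest other 16) of silencing. Of the differences between days, 1 of 100 splits reached the 963 genes of silencing (highest other 795) and 2 of 100 reached the 47 of the MCU vector, where another split called 79. Each count was reached by a share of splits under 0.05, which argues only against no difference of any kind between the groups. Real differences widen the spread within the other splits and so lower their counts. For the differences between days the splits exchange treated and control fibres, so they do not test whether the effects of the days are equal. For transfected control against wild type the real split is also the split by slide. A split that follows animals is not excluded.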

How the results depend on the processing

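The alternatives with wild type as control for silencing, with the Myh4 and Myh1 covariate and with list tests of silencing at 7 days alone were chosen after seeing the data. All others were chosen before the data were examined. No gene or Mcu value that passed in the main fit or the alternative reversed direction, and no correlation did. With another control group no single gene but Mcu was tested, and treated and control fibres were on different slides, so slide and group cannot be told apart. For Rrad, Ankrd1 and Myc the means of silenced fibres lay below transfected controls but above wild type. The balance of higher and lower calls turned with median scaling, from 56.7% to 25.1% higher for silencing and from 36.9% to 66.9% for transfected control against wild type. For silencing over both days it also turned with wild type as control (1163 higher, 1877 lower) and with only the groups compared (799 and 813), at 14 days over probes detected on all arrays (613 and 339), at 7 days with median scaling (967 and 1585), and for the difference of the vectors with median scaling (1917 and 518), normexp (1422 and 1299) and without MCU-vector day 7 replicate 1 (884 of 1704 higher). Of the gene values named under the alternatives, fits with a fibre left out included, 16823 kept their side of the threshold, 590 lost the call and 198 gained it. A change of direction was looked for only where a fit called the gene. Of the counts of genes and lists, Mcu values and correlations 280 did not move beyond the rule for a change (1.5 times for counts) and 26 did. Fits with a fibre left out are not in these 2 numbers, and those that moved are given below. The causes were not tested, except that fits of only the groups compared use fewer fibres.

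Counts for the MCU vector over both days were 492 with normexp, 1298 with array weights, 533 with the myosin covariate and 6057 against transfected controls. At 7 days the count was 343 with array weights; at 14 days it was 392 with array weights, 60 with only the groups compared, 39 with the share of detected probes and 568 with the myosin covariate. The day difference was 77 with normexp, 28 with detection on 15 arrays and 96 with array weights. Counts for silencing with only the groups compared were 1612 over both days, 851 at 7 days, 130 at 14 days and 323 for the day difference; with array weights they were 1818 at 7 days and 530 for the day difference; at 14 days they were 424 with the myosin covariate and 2353 against wild type. Transfected control against wild type gave 3569 with the share of detected probes and 2931 with slide as a random block (correlation within slides 0.132). Lists called with an estimated correlation numbered 2 for the MCU vector and 1 for silencing, and with fry 2 for the MCU vector. The correlation between days of the MCU vector was 0.251 without a filter.

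With replicate number as a block the counts were 260 and 3206 over both days, 134 and 105 for the MCU vector and 3010 and 818 for silencing at 7 and 14 days, 43 and 884 for day differences, 2604 for the difference of the vectors and 6453 for transfected control against wild type; with slide as a block 186 and 2643 over both days.

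Leaving out each fibre in turn gave counts of 171 to 309 for the MCU vector over both days, 115 to 146 at 7 days, 45 to 146 at 14 days and 30 to 54 for the day difference. For silencing they were 2484 to 3695, 1900 to 3270, 476 to 1019 and 701 to 982. The difference of the vectors gave 1704 to 3156, transfected control against wild type 5642 to 6628, lists 10 to 15 and 8 to 12. Mcu ranged from 2.17 to 2.34 and from -2.79 to -2.31 over both days, from 0.44 to 0.70 and 3.80 to 4.07 with the MCU vector, and from -2.48 to -1.54 and -3.50 to -2.68 with silencing. Counts moved over 1.5 times without wild type day 14 replicate 3 (45), MCU-vector day 14 replicates 2 (61), 3 (58) and 4 (48), MCU-vector day 7 replicates 1 (172, and 1704 for the difference of the vectors), 2 (171) and 3 (30, day difference), transfected control day 14 replicate 4 (528) and silenced day 7 replicate 3 (1900) and day 14 replicate 3 (476). Signal over background limits what is known of dim probes.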

Other observations

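The genes with 2 separate levels were chosen only after the result was seen. In 61 genes the fibres fell into 2 levels at least 1 log2 unit apart that never mixed within a group, against at most 1 gene in 20 random regroupings. MCU-vector fibres of 7 days stood apart from all other groups in 42 of them, all called higher at 7 days, among them the class II genes H2-Ab1, H2-Eb1 and H2-DMa, the immunoproteasome subunits Psmb8 and Psmb9 and the GTPases Irgm1, Irgm2, Igtp and Tgtp1. Of these genes 13 parted silenced from transfected control fibres on a day, 2 in the same direction on both days and 1 in opposite directions. That gene, Abcc9, was lower at 7 days (-2.39) and higher at 14 days (2.58). Wild type fibres of 7 and 14 days, on different slides, were themselves parted by 7 genes, among them Tmem14c and Ppp1r1c. Glud-ps and Ifit3 were low in transfected controls of 7 days alone.

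Stat3, a transcription factor of cytokine signalling, was higher than in wild type by 1.86 in transfected controls and by 0.99 with the MCU vector, and silenced fibres differed from transfected controls by -1.49.

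The mean signal of negative control spots was 25.5 on the array of silenced day 14 replicate 2 and between 14.0 and 16.3 on all others. Probes for Myh2, a fast myosin, were well above background on 2 of 30 arrays and those for the embryonic myosin Myh3 on 2 and 3.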
